A study of Mus musculus with 6 samples.

How the data were processed

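Messenger RNA from mouse placentas taken on gestational day 18 was sequenced in 6 libraries, 3 labelled control and 3 labelled arsenic. Sodium arsenite, an inorganic arsenic salt, was given in the drinking water of the pregnant mice from day 0 to day 18, per the labels' protocols. Those protocols list concentrations of 0, 0.15, 1.5 and 15 mg/L, and the concentration behind the arsenic libraries is not given in the sources used here. RNA was extracted with Trizol and DNase-treated, and strand-specific poly(A) libraries came from an Illumina TruSeq kit, per the labels' protocols. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program and the gene annotation are not given in the sources used here.

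The deposited tables hold a normalised signal per library for 20938 genes and 36574 RefSeq transcripts. Every value in a library was a whole multiple of 1 step, within a tolerance of 0.001 reads, so whole reads were recovered for 100% of values. The authors' size factors, taken from those steps, equalled median-of-ratios factors recomputed from the recovered reads and lay between 0.910 and 1.16. Totals of the recovered reads were 116077537, 95385235 and 121874146 in control libraries 1 to 3. They were 104910994, 104895206 and 116465456 in arsenic libraries 1 to 3. The reads of each of the 20938 genes equalled the sum of its transcripts. The values are called normalised read counts here. Intervals and limits from read numbers cover counting error only, since the reads carry no molecular identifiers.

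Libraries were compared within groups by a chi-square test per gene on the recovered reads, for genes with at least 30 reads over the libraries compared. The median over genes was set against the median that sampling alone gives. The test was checked on simulated reads of 20938 genes. It returned a median of 1.38 for 3 libraries drawn independently and 0.346 for 3 libraries that shared 75% of their reads. The 3 arsenic libraries differed by less than sampling noise, while the controls did not, so their mean entered the tests as 1 sample. The plan written before the data were examined had counted 6 separate samples. That analysis is given as an alternative.

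Genes were tested with limma-trend (limma 3.58.1 in R 4.3.3) on log2(normalised read count + 1), for the 17650 genes with a mean of at least 1. The model had 4 samples, 3 controls and the mean of the arsenic libraries, with 2 residual degrees of freedom. It assumes that the lone arsenic sample varies like the controls. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The labels call the samples biological replicates and do not tie them to separate litters. The 2 residual degrees of freedom come from the 3 controls, so the p-values measure the spread between these controls and none between arsenic samples. Transcripts went through the same test, with 29173 tested.

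The analysis used 42 gene lists fixed before the data were examined, on pathways linked with arsenic, on placental hormones and transporters, and on markers of the cell types a placental piece can hold. Of these, 40 were tested with camera at a preset inter-gene correlation of 0.01. Camera sets the members of a list against the other genes, so its p-values hold no spread between arsenic samples either. The list of fetal sex genes was used as a covariate only, and the table had no mitochondrially encoded gene to test. Camera with an estimated correlation and fry were alternatives. Genes named in the text followed a rule set at the same time. It took the gene in the study title, up to 12 genes per direction past the threshold, or, with fewer than 6, the 6 of smallest p, and up to 4 members of smallest p from each list. Predicted genes were counted without being named. Genes named outside that rule are marked as chosen after their values were seen.

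The limma step was tested on simulated data for the comparison of 3 controls with 1 sample, over 17315 genes with the spread of the controls. It called 0% of genes changed 2-fold, 8% of those changed 4-fold, 44% of those changed 8-fold and 80% of those changed 16-fold. Camera recovered the 1 shifted list of that simulation with 0 of the other 40 lists called. The simulated genes were drawn independently of each other, so this could not show how camera behaves with correlated genes. In the data the estimated correlation was 0.84 for yolk sac endoderm markers and 0.46 for the stress responses. For some other called lists it lay under the preset value, such as -0.066 for sinusoidal giant cell markers and 0.007 for CCN and YAP targets. Calls of those lists also ended with an estimated correlation, so the size of the correlation alone does not explain the loss. Further tests on the recovered reads used edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, with the arsenic reads summed. Alternatives covered other scalings, filters and pseudocounts, limma variants, covariates, each library left out and a replicate block. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. Of the 20938 gene names, 20721 were found in the RefSeq table of GRCm38.p6, the assembly called mm10, which gave the coordinates. Prolactin, Psg, Ceacam, cathepsin, globin and Dmrtc1 genes belong to families of near-identical copies, so reads can be shared between members and their single values are uncertain. No file of another series was used, and a note sheet without values was left out.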

Results

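Gene expression was measured in placentas of mice on gestational day 18 to compare dams given arsenite in their drinking water with control dams, in a search for a regulatory molecule. The series title names CYR61, a secreted matricellular protein, and m6A, a methyl mark on RNA. There were 3 control and 3 arsenic libraries, with 95385235 to 121874146 assigned reads each. The 20 most abundant genes took 14.0% to 16.5% of the total in the controls and 19.96% to 19.97% in the arsenic libraries. Values below are normalised read counts, with the mean ± SD of the 3 controls.

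The 3 arsenic libraries differed from each other by less than the sampling noise and were counted as 1 sample. Over 15685 genes their median chi-square per gene was 0.336, against 1.39 expected from sampling, and 1.63% of genes passed the 5% point. The median was 69.9 for the 3 controls, with 91.9% of genes past that point. Across genes, Spearman's rho lay between 0.9992 and 0.9995 for pairs of arsenic libraries and between 0.968 and 0.984 for pairs of controls, with genes not being independent replicates. The comparison thus set 1 arsenic sample against 3 controls.

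**Figure D1:**
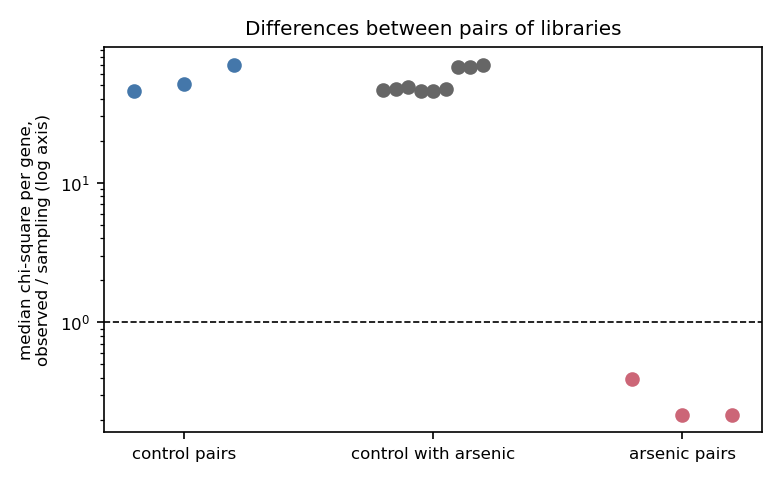
Median chi-square per gene for each pair of libraries, divided by the value sampling alone gives (vertical log axis, dashed line at 1), for control pairs, mixed pairs and arsenic pairs. The arsenic pairs lie at 0.39, 0.22 and 0.22, below the line, and the control pairs between 45.3 and 69.5.

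The arsenic sample was higher than the controls in the gene lists of prolactin family hormones and pregnancy-specific glycoproteins. It was also higher in the joint list of unfolded protein and integrated stress responses. The rise there lay mainly in 9 genes of endoplasmic reticulum lumen proteins, set apart after the values were seen (median log2 fold change 1.26). The 13 integrated stress response genes had a median of 0.06. The arsenic sample was lower in the lists of CCN genes and YAP targets, which include Cyr61, of labyrinth syncytiotrophoblast and decidual stroma, and of nutrient and metal transporters. No single gene passed the test after adjustment, so gene values below stand as values. Gene lists passed a set test with a preset correlation, 16 of 40, and 0 of 40 with an estimated correlation. The preset test also called 3, 6 and 8 lists when control 1, 2 or 3 was set against the other 3 samples. Yolk sac transcripts and Y-linked transcripts also differed between the arsenic sample and 2 of the 3 controls, as described below.

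Cyr61 is listed under its current symbol Ccn1 (NM_010516; mm10 chromosome 3, 145646971 to 145649985, protein-coding). Ccn1 lay at 27706, 28657 and 24329 in the controls (26897 ± 2275, n = 3) and at 15071, 15129 and 15087 in the arsenic libraries, whose mean of 15096 was 0.561 of the control mean. Its log2 fold change was -0.83 (SE 0.14, 95% interval -1.25 to -0.41), and limma gave an adjusted p of 0.918 and rank 103 among 17650 genes by p. An exact two-sided permutation test on the 4 samples gave p = 0.25, the smallest this design allows. With the 6 libraries counted as separate samples, limma gave Ccn1 an adjusted p of 0.0052. That fit counts near-identical arsenic libraries as replicates, so this p-value overstates the evidence. DESeq2 on the 4 samples gave a log2 fold change of -0.83.

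Ccn2, Ccn3 and Ccn4 lay below all 3 controls as well, and Ccn5, chosen after its values were seen, within their range. Ccn2, which encodes connective tissue growth factor, lay at 22595 against 58788 ± 13271 (log2 fold change -1.35). Ccn3 lay at 518 against 1398 ± 446 and Ccn4 at 618 against 1079.6 ± 136. Of the 20 tested members of the list of CCN genes and targets of YAP, a co-activator of the Hippo pathway, 12 lay below all controls and 0 above, with a median log2 fold change of -0.25. Camera gave the list an adjusted p of 2.8e-04, and an adjusted p of 0.44 with an estimated correlation. Immediate early genes, induced within minutes of a stimulus, had 12 of 26 members below all controls and 4 above (median -0.16, camera adjusted p = 0.026, and adjusted p = 0.59 with an estimated correlation). Fos lay at 5206 against 12852 ± 3604 and Klf2, a flow-responsive factor, at 3097 against 4683 ± 483. Against control 2 alone the medians of both lists were -0.21 and -0.16, and the call of the immediate early list ended without control 1 or control 2 (medians -0.13 and -0.17, camera adjusted p = 0.061 and 0.068). Without control 3 the medians were -0.16 and -0.25. Both calls ended with the fetal sex covariate (medians -0.21 and -0.16, camera adjusted p = 0.058 and 0.17), and that of immediate early genes with the yolk sac score as well (median -0.17, camera adjusted p = 0.084).

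**Figure D2:**
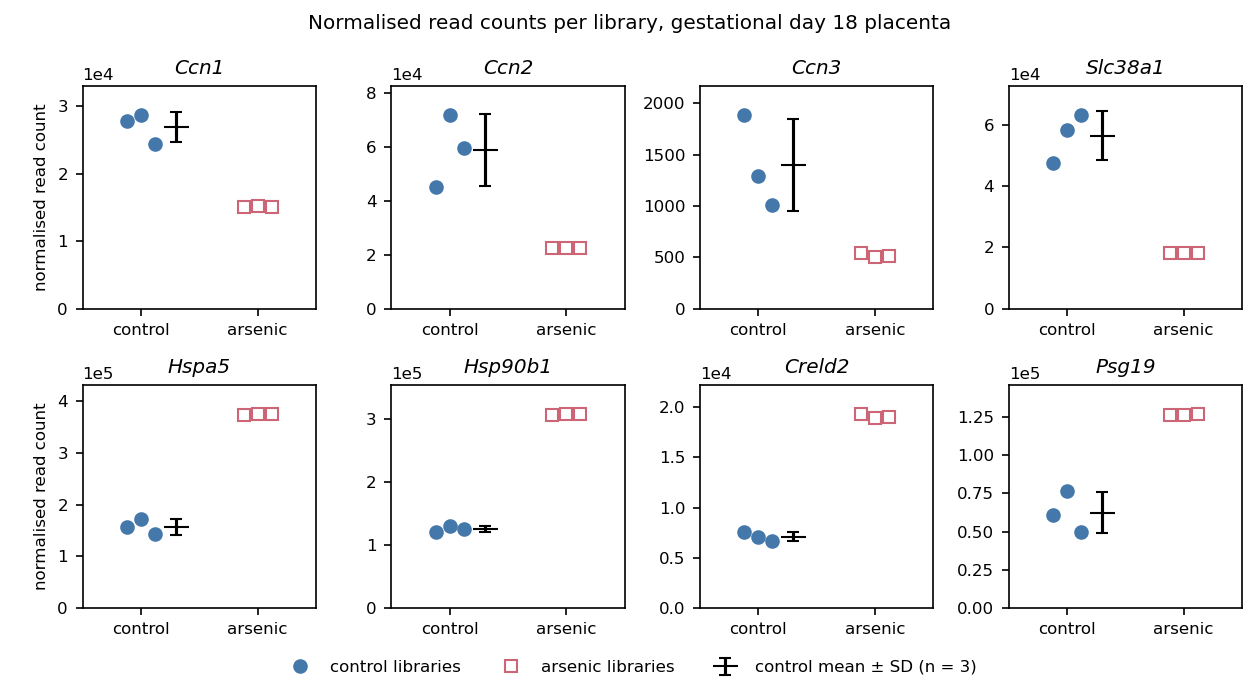
Normalised read counts (vertical axes from 0) of 8 genes in each control library (filled circles) and arsenic library (open squares), with the control mean ± SD (n = 3). Ccn1, Ccn2, Ccn3 and Slc38a1 lie below every control in the arsenic libraries, and Hspa5, Hsp90b1, Creld2 and Psg19 above.

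Limma called 0 of 17650 genes. At an unadjusted p under 0.05 there were 955 genes, 406 higher and 549 lower, with 882.5 expected by chance. The arsenic sample lay above all controls in 4277 genes and below all in 3963, together 46.7% of genes, where chance without ties gives 50%. On the recovered reads edgeR called 0 genes (751 at an unadjusted p under 0.05) and DESeq2 called 208, 54 higher and 154 lower. DESeq2 also called 46, 269 and 351 genes when control 1, 2 or 3 was set against the other 3 samples. Limma called 2105 genes with the 6 libraries counted as separate samples, 1005 higher and 1100 lower.

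None of the named genes of smallest p passed the threshold. On the higher side, Creld2, an endoplasmic reticulum protein, lay at 19120.1 against 7112 ± 421 (log2 fold change 1.43), Sdf2l1 at 7901 against 3129.7 ± 233 and Hsp90b1, the chaperone GRP94, at 307343 against 125250 ± 4917. Nucb2, the nesfatin precursor, lay at 17078 against 7973 ± 352. Mfsd2a, a lysophospholipid transporter, lay at 6139 against 3604 ± 124 and Dnah11, an axonemal dynein, at 363 against 24.6 ± 5.79, although Dnah11 overlaps the protein-coding gene Cdca7l and its assignment is uncertain. On the lower side, Ano1, a calcium-activated chloride channel, lay at 2463 against 4989 ± 90.7. Acvr1c, Htd2 and Cenpk were at 0 reads in all arsenic libraries, against control means of 49.5, 109 and 105. Against a floor of 3 reads per library they were at least 15.8-fold, 34.9-fold and 33.5-fold lower. Htd2 shares its locus with Rpp14, which lay at 3275 in the arsenic sample and 2807 to 3447 in the controls, and Cenpk overlaps Ppwd1, so both assignments are uncertain. Cdca7l, Rpp14 and Ppwd1 were chosen after values were seen, for their position. The near-identical X-linked copies Dmrtc1c1 and Dmrtc1c2 lay at 3.13 and 0, against 424 ± 59.3 and 463 ± 138 in the controls.

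Of 24 tested genes of the unfolded protein and integrated stress responses, 17 lay above all controls and 4 below. The median log2 fold change was 0.30 (camera adjusted p = 2.7e-05, and adjusted p = 0.67 with an estimated correlation). No member passed over all genes tested, and 9 passed when adjusted over the list alone: Creld2, Sdf2l1, Nupr1, Hsp90b1, Pdia6, Hspa5, Pdia4, Calr and Manf. Hspa5, the main chaperone of the endoplasmic reticulum, lay at 374672 against 157121 ± 14921 (log2 fold change 1.26), the disulfide isomerases Pdia4 and Pdia6 at 51793 against 20795 ± 3386 and 175767 against 81155 ± 6396, and Calr at 293033 against 144946 ± 12777. Hspa5, Pdia4, Pdia6, Calr and Manf were chosen after their values were seen, and Hspa5, Pdia6 and Ddit3 overlap other protein-coding genes. Other members went elsewhere. Nupr1, a stress-induced transcriptional cofactor, lay at 1333 against 2812 ± 138, and Atf4 and Ddit3, transcription factors of the integrated stress response chosen after their values were seen, had log2 fold changes of 0.06 and 0.26. Against control 2 alone the list median was 0.16, and without control 3 it was 0.17. The call ended with the fetal sex covariate (median 0.16, camera adjusted p = 0.052).

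Placental hormone genes were higher in the arsenic sample. Among pregnancy-specific glycoproteins and CEACAMs, immunoglobulin-like proteins secreted by trophoblast, 14 of 21 lay above all controls and 0 below, with a median of 0.81 (camera adjusted p = 2.5e-08, and adjusted p = 0.44 with an estimated correlation). Psg19 lay at 126584 against 62474 ± 13346 and Ceacam13 at 235848 against 120572 ± 9726. Among prolactin family hormones 15 of 25 lay above all controls and 1 below, with a median of 0.52 (camera adjusted p = 2.1e-05, and adjusted p = 0.44 with an estimated correlation). Prl2b1 lay at 283938 against 108206 ± 21341, Prl8a8 at 303833 against 175323 ± 13502 and Prl7a1 at 4202 against 2457 ± 161. Against control 2 alone the medians of these lists were 0.73 and 0.53. Markers of the cells that make these hormones were higher too. Sinusoidal giant cell markers had 9 of 12 above all controls (median 0.62, camera adjusted p = 2.1e-05, and adjusted p = 0.44 with an estimated correlation), with the cathepsins Ctsm at 52987 against 32275 ± 2009 and Cts3 at 341445 against 184002 ± 25673. Spongiotrophoblast and parietal giant cell markers had 13 of 19 above and 1 below (median 0.50, camera adjusted p = 9.2e-05, and adjusted p = 0.44 with an estimated correlation). The exception was Phlda2, an imprinted growth suppressor, at 408 against 1127 ± 263. That list shares 9 of its 19 tested genes with the hormone lists, and its call ended with the fetal sex covariate, with a median of 0.49 (camera adjusted p = 0.055).

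Markers of labyrinth syncytiotrophoblast, the layer between maternal and fetal blood, had 12 of 19 below all controls and 1 above (median -0.52, camera adjusted p = 2.1e-05, and adjusted p = 0.44 with an estimated correlation). Synb, the fusogen syncytin B, lay at 6781 against 11258 ± 901 and Gjb2, the gap junction protein connexin 26, at 55797 against 90649 ± 4916. Nutrient transporters had 18 of 30 below and 4 above (median -0.25, camera adjusted p = 9.9e-04, and adjusted p = 0.44 with an estimated correlation). The amino acid transporter Slc38a1 lay at 18203 against 56363 ± 7981, Slc1a4 at 9741 against 14118 ± 1343 and the glucose transporter Slc2a3 at 2575 against 4732 ± 903, while Mfsd2a was higher. Genes of metallothioneins and metal transport had 9 of 18 below and 2 above (median -0.29, camera adjusted p = 0.026, and adjusted p = 0.44 with an estimated correlation). The iron exporter Slc40a1 lay at 27423 against 44596 ± 1049 and the transferrin receptor Tfrc at 88058 against 150950 ± 33228. That call ended without control 2 (median -0.30, camera adjusted p = 0.14), and the call of nutrient transporters with the fetal sex covariate (median -0.21, camera adjusted p = 0.055). Against control 2 alone the medians of these 3 lists were -0.31, -0.21 and -0.43.

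Decidual stroma markers, genes of the maternal side, had 13 of 19 below all controls and 0 above (median -0.56, camera adjusted p = 9.9e-05, and adjusted p = 0.44 with an estimated correlation). Wnt4 lay at 2163 against 3407 ± 558 and the progesterone receptor gene Pgr at 1853 against 3413 ± 910.2. P53 targets had 13 of 20 below and 2 above (median -0.28, camera adjusted p = 0.0083, and adjusted p = 0.44 with an estimated correlation), with Plk2 at 4140 against 5108 ± 177. Genes of cholesterol and fatty acid synthesis had 12 of 25 below and 2 above (median -0.25, camera adjusted p = 0.012, and adjusted p = 0.80 with an estimated correlation), with Idi1 at 543 against 1054 ± 78 and Dhcr24 at 8202 against 14347 ± 2465. Endothelial markers had 12 of 19 above and 2 below (median 0.28, camera adjusted p = 0.0041, and adjusted p = 0.59 with an estimated correlation). Esam lay at 22389 against 16642 ± 428, and Kdr, the main VEGF receptor, at 8483 against 12215 ± 560.2. Of 3 embryonic globins 2 lay above all controls (median 1.95, camera adjusted p = 0.025, and adjusted p = 0.57 with an estimated correlation), with Hbb-y at 295 against 48.3 ± 14.2. The calls of endothelial markers and embryonic globins ended without control 2 (medians 0.20 and 1.61, camera adjusted p = 0.052 and 0.071), and that of cholesterol and fatty acid synthesis without control 1 (median -0.15, camera adjusted p = 0.093). With the fetal sex covariate the globin median was 2.62 and the cholesterol median -0.08, and both calls ended (camera adjusted p = 0.055 and 0.44). The cholesterol call also ended with the yolk sac score (median -0.07, camera adjusted p = 0.19). Against control 2 alone the decidual median was -0.87, the endothelial 0.48, the p53 -0.28 and the cholesterol median -0.08.

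**Figure D3:**
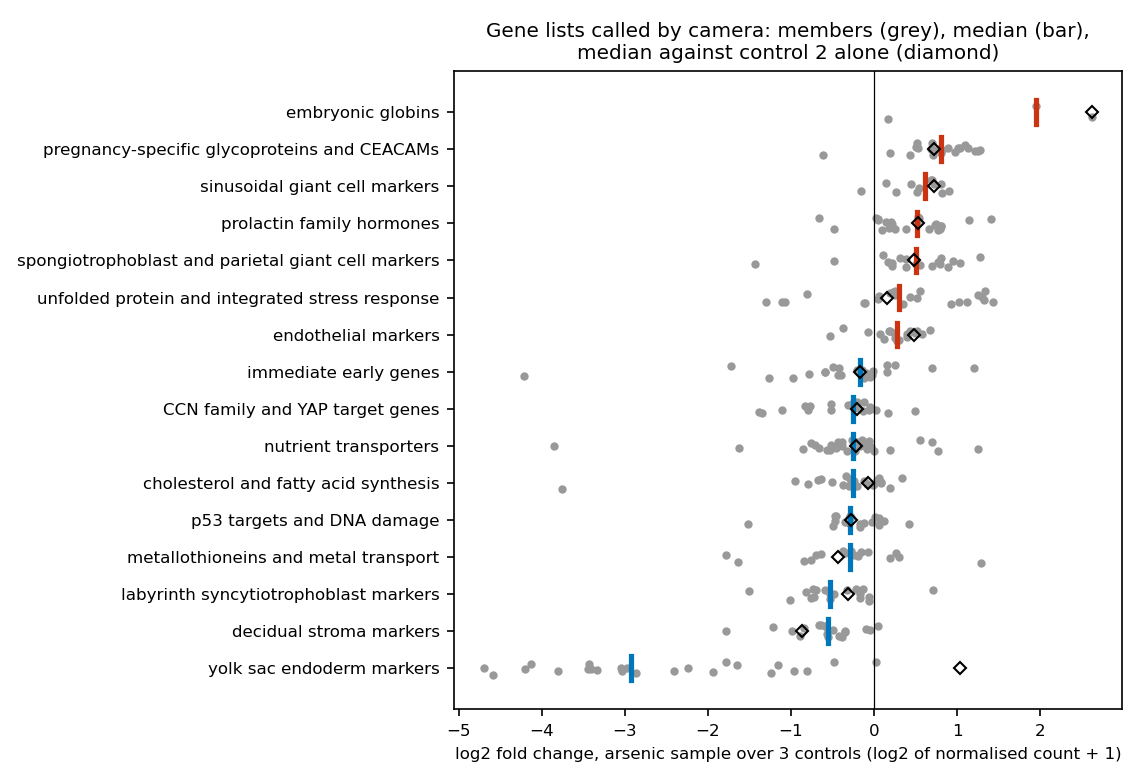
Log2 fold changes, arsenic sample over the 3 controls, for the members (grey points) of the 16 gene lists called by camera with a preset correlation, with each list's median (coloured bar) and its median against control 2 alone (diamond). The bar and the diamond lie on opposite sides of 0 for yolk sac endoderm markers, at -2.92 and 1.03, and on the same side for the other lists.

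Genes of the m6A machinery were not called as a list, which with 1 arsenic sample does not show that a shift was absent. Of 23 tested writers, erasers and readers, 9 lay above all controls and 3 below, with a median of 0.07 (camera adjusted p = 0.34). The reader genes Igf2bp2 and Igf2bp1 lay at 6913 against 12438 ± 1996 and at 9833 against 7259 ± 937. The libraries measured transcript levels and not the m6A mark itself. The list of NRF2 and oxidative stress genes had a median of -0.06 (camera adjusted p = 0.34), although Gpx3, a secreted glutathione peroxidase, lay at 58243 against 198925 ± 36587. The list of arsenic transport and methylation had a median of -0.01 (camera adjusted p = 0.63), with the efflux pump gene Abcb1a, which overlaps another protein-coding gene, at 2094 against 3848 ± 297, the aquaglyceroporin gene Aqp3 at 5492 against 4216 ± 109 and Gsto1 at 3991 against 5095 ± 303. Heat shock proteins (median 0.13), inflammatory cytokines (median -0.11), interferon-stimulated genes (median -0.05), hypoxia genes (median -0.06), angiogenesis factors (median 0.09) and cell cycle genes (median 0.03) had camera adjusted p-values of 0.30, 0.995, 0.78, 0.63, 0.77 and 0.78. The other 15 lists, among them collagens, imprinted genes, oxidative phosphorylation and markers of immune, muscle, fibroblast and glycogen cells, had medians from -0.39 to 0.31 and camera adjusted p-values from 0.12 to 0.77. Median and mean differed in sign for angiogenesis factors, interferon-stimulated genes, glycogen trophoblast markers and fibroblast markers, and the inflammatory list had a negative median with a test direction of higher.

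Yolk sac endoderm markers separated the controls from each other. Afp, which encodes alpha-fetoprotein and was chosen after its values were seen, lay at 2589732 and 2235787 in controls 1 and 3, at 4609 in control 2 and at 16187 in the arsenic sample. The list median was -2.92 (camera adjusted p = 2.8e-04, and adjusted p = 0.86 with an estimated correlation), with 20 of 24 members within the range of the controls. Against control 2 alone the median was 1.03, and 19 of 24 members lay above that library, while without control 2 it was -5.00. Y-linked genes split the samples the same way. Ddx3y lay at 227, 5905 and 27.6 in controls 1 to 3 and at 7894 in the arsenic sample. Control 2 was thus the only control with both low yolk sac and high Y-linked transcripts, as in the arsenic sample. Adding fetal sex as a covariate left control 2 as the reference, with 11 of 40 lists called.

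**Figure D4:**
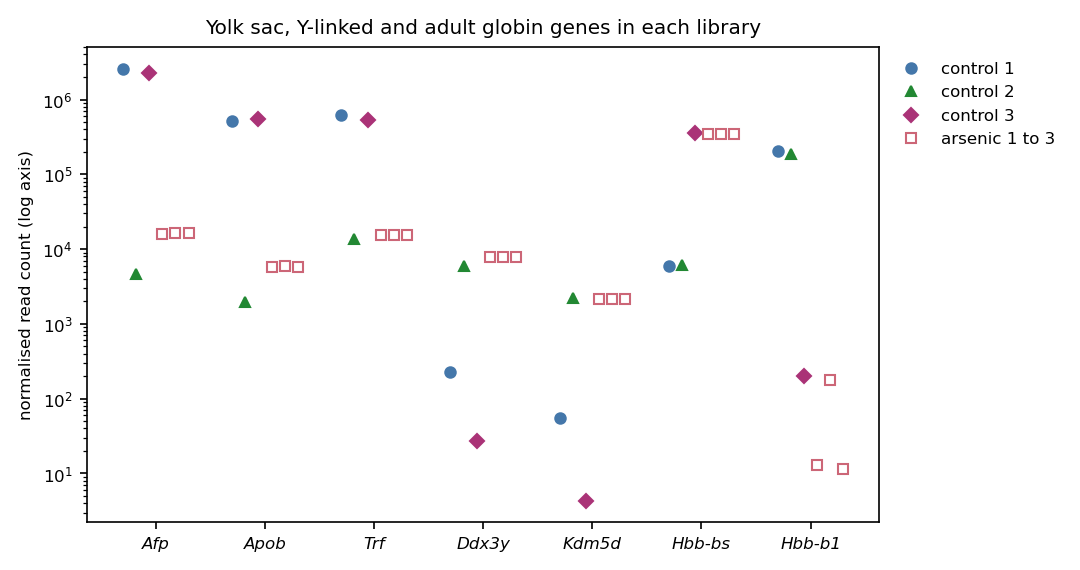
Normalised read counts (log axis) of yolk sac genes (Afp, Apob, Trf), Y-linked genes (Ddx3y, Kdm5d) and adult beta globin genes (Hbb-bs, Hbb-b1) in each library. Afp, Apob and Trf were chosen after their values were seen. The arsenic libraries lie with control 2 for yolk sac and Y-linked genes and with control 3 for Hbb-bs.

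The transcript table gave 0 of 29173 transcripts past the threshold in limma, with 1968 at an unadjusted p under 0.05. The Ccn1 transcript had a log2 fold change of -0.83. With the 6 libraries counted as separate samples, 3168 transcripts passed.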

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

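Alternatives with edgeR, DESeq2, a yolk sac score covariate, a mean of at least 100 and control 2 alone were chosen after seeing the data. The 6 libraries without a replicate block were planned as the main analysis, and only their use as an alternative was decided after the libraries were compared. A replicate block was planned. The count of 0 called genes by limma held under other scalings, filters, pseudocounts and limma variants, under fetal sex and yolk sac covariates, and with each library left out (0 to 0 genes). It also held in edgeR, and became 208 genes with DESeq2, 487 (179 higher, 308 lower) at an unadjusted p under 0.05 with a 2-fold change, 2105 with the 6 libraries as separate samples in limma and 1878 in edgeR (867 higher, 1011 lower) on near-identical arsenic libraries.

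The deviations of same-numbered libraries correlated at 0.018, 0.019 and 0.034, although each of the 3 arsenic libraries correlated best with its own number. With the 6 libraries and a replicate block, limma called 0 genes, 441 transcripts and 16 lists, and gave Ccn1 an adjusted p of 0.066.

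Ccn1 kept a negative log2 fold change under all 28 alternatives, from -0.93 to -0.78 (-0.90 to -0.78 with a library left out). The filters, limma without trend and robust limma return the same fold change by construction. Ccn1 lay below all controls, so leaving a control out could not turn its sign. The gene passed the threshold in DESeq2 (-0.83, adjusted p = 0.0045) and with the 6 libraries in limma (-0.83, adjusted p = 0.0052) and edgeR (-0.83, adjusted p = 0.0059). Its adjusted p lay between 0.55 and 0.997 in the other fits except the blocked one. Transcripts called were 0 with each library left out (0 to 0) and 3168 with the 6 libraries as separate samples.

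Lists called stayed between 15 and 17 with a library left out and between 11 and 18 elsewhere, and became 0 with an estimated correlation and 0 with fry. Yolk sac endoderm markers turned to a median of 1.03 with the fetal sex covariate and against control 2 alone, since both leave control 2 as the reference. Their median lay between -5.00 (without control 2) and -1.77 with a library left out. Single libraries ended some list calls: immediate early genes without control 1 or 2 (median -0.13, adjusted p = 0.061, and -0.17, 0.068), cholesterol synthesis without control 1 (-0.15, 0.093), and metal transport (-0.30, 0.14), embryonic globins (1.61, 0.071) and endothelial markers (0.20, 0.052) without control 2. With the fetal sex covariate 7 of the 16 list calls were lost: CCN and YAP targets (median -0.21, adjusted p = 0.058), immediate early genes (-0.16, 0.17), stress responses (0.16, 0.052), nutrient transporters (-0.21, 0.055), spongiotrophoblast markers (0.49, 0.055), embryonic globins (2.62, 0.055) and cholesterol synthesis (-0.08, 0.44). That fit has 1 residual degree of freedom. The yolk sac score ended the calls of immediate early genes (-0.17, 0.084) and cholesterol synthesis (-0.07, 0.19), and by construction that of the yolk sac list it is made from. Of 78 named genes followed, 74, Ccn1 included, kept their direction under each alternative, and 42 passed in DESeq2 and 70 with the 6 libraries in limma. No exception passed. Afp turned to 1.81 with the fetal sex covariate and 0.25 with the yolk sac score, which includes it. Atf4 and Xbp1 turned to -0.038 and -0.045 with scaling to the library total and to -0.047 and -0.045 in edgeR without factors, and Atf4 to -0.020 with array weights. With a library left out Atf4 lay between -0.047 (without control 3) and 0.16, and Ccn5 between -0.18 (without control 2) and 0.89; the cause was not tested. Depth limits the genes at 0 reads, where 3 reads per library equal 3.13 normalised counts.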

Other observations

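The calls of gene lists were planned. The tests of explanations in this part were chosen after the results were seen, as were the genes Hba-a1, Cwc22, Jund, Dag1, Afp, Herpud1, Xbp1 and the albumin gene.

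Values of single genes differed between libraries in ways the groups do not explain. Among genes with a mean of at least 100 in the controls, 1955 of 13647 differed over 2-fold between the controls. Adult beta globin genes appeared in different forms: Hbb-b1 lay at 207654 and 185876 in controls 1 and 2 and at 201 and 67.9 in control 3 and the arsenic sample, while Hbb-bs lay at 5879 and 6051 against 355831 and 346783. The alpha globin gene Hba-a1 lay at 2.2 in control 2 and at 57489 or more in the other samples. Cwc22, a splicing factor gene, lay at 31945 in control 2 and 4695 in control 1. Jund, an AP-1 gene, lay at 571 in control 1 and 340 in the arsenic sample, against 20525 and 21691 in controls 2 and 3. Globin genes have near-identical copies that can share reads, so a low value of a copy need not mean low expression. Whether read assignment or expression gave these differences was not tested. Other genes set the arsenic sample apart from all 3 controls, as 46.7% of all tested genes did, where chance without ties gives 50%. Among imprinted genes, a list not called, 8 of 26 lay above all controls, such as Slc38a4 (143616 against 98478 ± 16932) and Sfmbt2 (32166 against 26048 ± 2322), and 7 below, such as Phlda2 and the cation transporter gene Slc22a3 (3787 against 6167 ± 634). The prostaglandin synthase gene Ptgs2 lay at 1126 against 2383 ± 252 and Tnf at 339 against 149 ± 18.8. Rbp4, the plasma retinol carrier, lay at 24267, 12669.5 and 21603 in the controls and at 2385 in the arsenic sample, below control 2 as well, unlike most yolk sac markers.

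Within the list of stress responses the members split by kind of protein, a division made after the values were seen. All 9 proteins of the endoplasmic reticulum lumen lay above all controls (median log2 fold change 1.26, and 1.12 against control 2). The 13 transcription factors and targets of the integrated stress response had a median of 0.06, with 6 above and 4 below. The other 2 members, Herpud1 and Xbp1, lay above all controls, with log2 fold changes of 0.56 and 0.05.

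The arsenic libraries are closer than sampling allows. The ratio of observed to expected chi-square should be above 1 for 3 separate placentas and about 1 for 1 library read 3 separate times. Its highest value over the depth bins was 0.42, which argues against both. Reads held in common between the columns would give a ratio below 1, as the 0.243 over all genes is, so the columns may be overlapping samples of 1 set of reads. Even so, 46 of 13334 genes differed over 2-fold between the arsenic libraries, such as Dag1 at 36597, 3567 and 3580, which was not explained.

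Yolk sac genes were high in controls 1 and 3. Yolk sac tissue in those pieces is a candidate explanation: 21 of 24 tested markers were 2-fold or more above control 2 in both. Albumin, abundant in fetal liver, lay at 7002 and 12995 there, far under Afp. Of the markers, 18 lay at 100 or more in control 2, and whether placental cells or remaining yolk sac gave those reads was not tested. A lowering by arsenic is not decided by these data: the arsenic sample lay above control 2, by a median log2 difference of 1.03, and that is 1 library. Fetal sex cannot be told apart from it, since low yolk sac and high Y-linked transcripts go together in 4 of 4 samples.

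Secretory trophoblast lists were higher in the arsenic sample. Dilution of the controls by yolk sac tissue would raise labyrinth syncytiotrophoblast markers alike, and their median of -0.52 (upper quartile -0.16), against a lower quartile of 0.23 over the 46 hormone genes, argues against it as the whole cause. A larger share of spongiotrophoblast and giant cells in the piece is a candidate that these values do not decide. Of 21 markers outside the hormone lists 71.4% lay above all controls, under the 75% set for this. Those 21 join markers of spongiotrophoblast, parietal giant cells and sinusoidal giant cells, whose shares were not tested apart. For the 9 endoplasmic reticulum lumen proteins the same share would give a rise no larger than that of the markers. Their lower quartile of 1.02 lies above the markers' upper quartile of 0.72 and highest value of 0.96. It also lies above the hormone genes' upper quartile of 0.81. Single hormone genes reached 1.41, and against control 2 alone the lower quartile was 0.88 and the highest marker 0.93. Calr, whose log2 fold change is the 1.02, went down to 0.54 among the alternatives. The 9 were set apart after the values were seen, so these values cannot decide whether that share is the whole cause. All 24 tested members of the stress list had a median of 0.30, below 0.52 for the markers. A change in cells that these markers do not cover stays open. An effect of arsenic is untested beyond 1 sample.

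With 6 libraries as separate samples, the real grouping gave 2105 genes and the highest of the other splits 1, and 1 of the 10 splits was as large. Only the real grouping keeps the near-identical arsenic libraries together, so this comparison of splits could not test a group difference. With 3 controls against the arsenic sample, 16 lists were called and at most 8 when a control was set apart, so 1 of 4 splits was as large. Both designs have too few splits for a share under 0.05.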
